A study of Mus musculus with 6 samples.

How the data were processed

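Gene expression was measured in ureters of 2-month-old mice on a C57BL/6N background, collected 4 days after unilateral ureteral obstruction, a procedure in which the ureter of 1 side is tied so that urine cannot drain. The labels assign 3 mice to the Col17a1-WT group and 3 to the Col17a1-KO group, and give a replicate number to each. The labels name 1 KO mouse, replicate 3, as female and the other 5 mice as male. Per the labels' protocols, total RNA was purified on columns, its integrity was checked, and Cy3-labelled cRNA was hybridised to 1-colour Agilent arrays, 1 array per mouse.

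Per the file headers, the spot intensity values were produced by Agilent Feature Extraction 12.0.3.1, which subtracted background and detrended each array and left the arrays unnormalised against each other. The deposited intensity columns used here were the processed signal for the main values and the mean signal with the local background for an alternative. Per the file headers, probe coordinates refer to the mouse genome build mm9. All 6 arrays lay on 1 slide and shared 1 scan time, so slide and scan could not act as batches. How the authors normalised between arrays is not given in the sources used here.

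Of the spots on each array, 59305 were not controls, and they represented 56605 probes. Spots flagged as outliers by the scanner software were set to missing and spots of a probe were averaged. The log2 processed signal was centred on each array's 75th percentile over non-control probes. Accessions of 35405 probes matched a symbol in the RefSeq table of assembly GRCm38.p6, which changed 1 symbol; the other 21200 probes kept the name in the files. Probes well above background on every array of at least 1 group were kept, and each gene was represented by its brightest probe, which left 22260 genes. Of these 15810 matched a reference symbol and 6450 did not. The latter include clone, region and transcript identifiers, which are counted as genes here although some share a locus. Between 35482 and 36567 probes per array were well above background and no spot was saturated. The number of arrays limits the precision.

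Genotype was tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 39 lists with at least 4 measured members, leaving out sex-linked genes. The same lists were tested with an estimated correlation and with limma's fry. An exact permutation test of 3 arrays against 3 has a smallest two-sided p of 0.1. Where a probe was not well above background on any array of a group, a fold is given as a bound, from the mean of the bright group against the mean, over the dim group's arrays, of the higher of the lowest well-measured signal on that array and the probe's own. Genes within 10 Mb of Col17a1 were compared with all other genes by a two-sided Fisher's exact test, and because fewer than 10 genes passed the adjusted threshold, a gene counted at an unadjusted p under 0.01.

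The lists, the tests described above and the rule for naming genes were fixed before the data were examined. Tests of explanations that were chosen only after the results were seen are named as such in the closing section. The rule names Col17a1, the 12 genes with the largest difference in each direction among those past the threshold, and the best-ranked members of each list (4 of a list past the threshold, up to 3 of another list). Because no gene passed, the 12 in each direction were taken from genes at an unadjusted p under 0.01, well above background on all 6 arrays and with no overlap between groups. Predicted, clone-based and sex-linked genes were left out of this part. Some genes named by this rule and a test of the immunoglobulin pattern are not reported here and are left out of the counts of named genes, so 11 are named by size in each direction. Among 145 named genes, 53 had more than 1 measured probe, and for 6 of them (Trp63, Lamb3, Fn1, Col1a1, Mbp and Notch1) probes differed in sign, as they did for Sfxn2, which was chosen after its values were seen.

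The procedure was tested on simulated data with the means of the 22260 genes in the KO against WT comparison. Their spread was set by limma's moderated variances, which vary less between genes than the genes' own. In 5 simulations with 200 changed genes besides the members of shifted lists, 57.2% of 2-fold and 92.6% of 4-fold changes were recovered. The mean was 10 false calls per run. Lists shifted by 0.8 in log2 were recovered in 15 of 15 cases, and 1 of 180 unshifted lists was called. The adjusted threshold depends on how many genes change, so these shares need not hold for the real data, where no gene passed. Genes were simulated as independent of each other, unlike the members of a list on real arrays. Alternatives covered background correction, normalisation, the filter on dim probes, probe choice, the variance model, array weights, sex, a replicate block, slide row, the set test and each array left out in turn. Since KO replicate 3 was the only female, a sex covariate removes that animal from the estimate. It is therefore not independent of leaving out that array and does not measure an effect of sex. Where the text names a further alternative as chosen after the data were seen, it was added later. Python 3.11.15 drew the figures.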

Results

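Ureter RNA from 3 Col17a1-WT and 3 mice labelled Col17a1-KO was compared 4 days after ureteral obstruction. Col17a1 encodes collagen XVII, a transmembrane component of hemidesmosomes, the structures that anchor basal epithelial cells to the basement membrane. The comparison asks which transcripts of the obstructed ureter differ with the Col17a1 genotype. The arrays gave 75th-percentile signals between 143.7 and 164.9. Correlations between arrays, taken across genes, ranged from 0.977 to 0.993, and no array duplicated another. Xist, expressed from the inactive X chromosome, had a value of 0.04 in KO replicate 3 and values between -7.37 and -7.17 in the other 5 arrays, which matches the labelled sexes.

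Col17a1 itself was not lower in the ureters labelled KO. Its brighter probe, on chromosome 19 at 47720894 to 47720953 (mm9), had a log2 value of -1.17 ± 1.02 in WT and 0.48 ± 0.06 in KO-labelled ureters (SD, 3 arrays each). The difference was 1.65 with a standard error of 0.48 (limma, adjusted p = 0.457), so it did not pass the threshold, although the groups did not overlap. The lowest WT value, -2.33, belonged to replicate 1, and without that array the difference was 1.07. The other probe, at 47721454 to 47721513, had values of -2.94 ± 0.35 and -1.83 ± 0.09. Both probes were well above background on all 6 arrays. The labels do not say which part of the gene was altered, and a probe outside the altered part does not check the genotype. The direction at these probes goes against the label, so the group is called KO-labelled here and every direction below rests on the labels alone.

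No single gene passed the threshold in limma. The lowest adjusted p was 0.229, and 2017 of 22260 genes had an unadjusted p under 0.05, where 1113 are expected by chance. Groups did not overlap for 15.4% of genes, against 10% expected by chance. None of the 22 genes named by size passed, and their adjusted p-values lay between 0.229 and 0.454. Among the higher genes were Ltf, a neutrophil granule protein, at 1.99 ± 0.37 (log2 difference and standard error), Adh7, an alcohol dehydrogenase, at 1.79 ± 0.19, Aldh3a1, an aldehyde dehydrogenase, at 1.75 ± 0.41, and Rbp4, a retinol carrier, at 1.68 ± 0.41. Adgrf4, Gsdma, Msln, Nqo1, H60c, Cfap43 and Calca followed, with differences between 1.41 and 1.61. Among the lower genes were Gdf3 at -1.86 ± 0.50, whose other probe differed by -0.13, Gpnmb, a glycoprotein of macrophages, at -1.85 ± 0.46, Atp6v0d2, a proton pump subunit, at -1.76 ± 0.38 with its other probe at -2.53, and Abcg3 at -1.50 ± 0.32. Blnk, H2-Eb1, Misp3, Cd74, Slamf8, H2-Ab1 and H2-Aa had differences between -1.42 and -1.31. With array weights limma called 498 genes, but the weights did not converge and differed up to 30.2-fold between arrays.

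**Figure D1:**
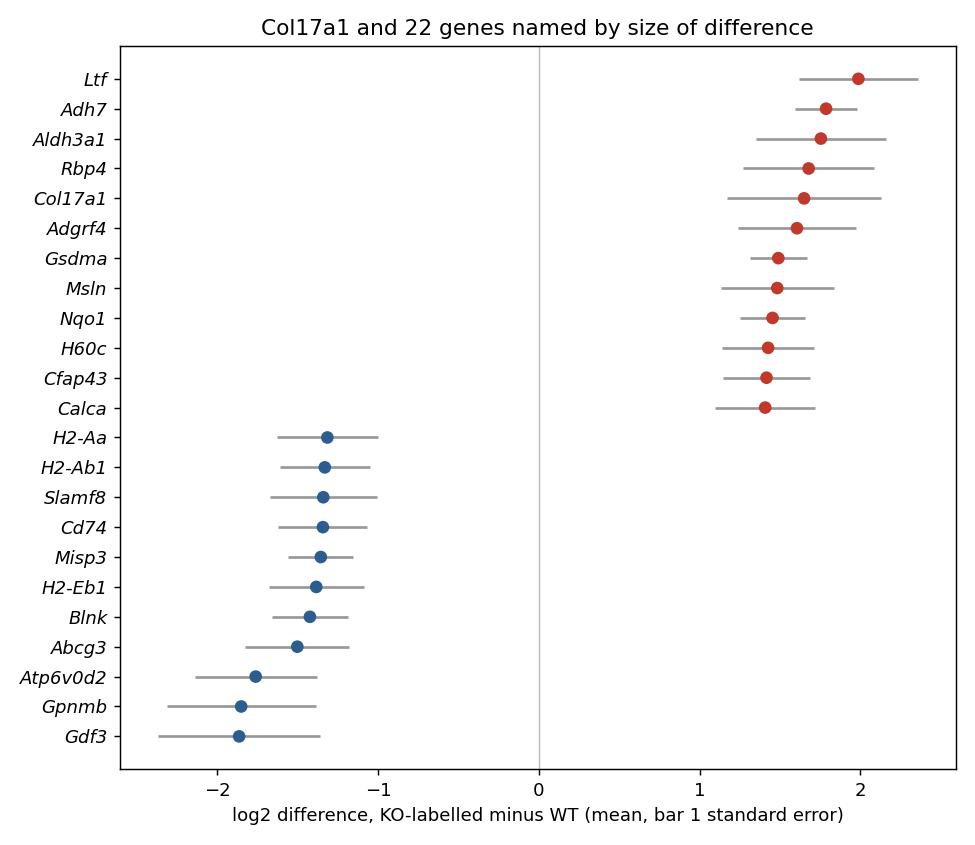
Log2 difference, KO-labelled minus WT, for Col17a1 and the 22 genes named by size, with points at the mean difference of 3 against 3 arrays and bars of 1 standard error. At each gene's brightest probe Ltf stands highest at 1.99 and Gdf3 lowest at -1.86, although another Gdf3 probe differed by -0.13, and no gene passed the adjusted threshold.

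Among 39 gene lists, 15 passed with camera's preset correlation, 11 toward higher and 4 toward lower values. None passed with an estimated correlation, where the smallest adjusted p was 0.587, and none passed with fry. For the antioxidant response list the estimated correlation was 0.0174, near the preset 0.01, yet camera's unadjusted p went from 3.26e-05 to 0.016. For this list the lost call therefore does not show that correlation among its members accounts for the preset-correlation call. The other passing lists had estimated correlations from 0.0445 for basal urothelium to 0.844 for smooth muscle, with 0.697 for MHC class II. There the part played by correlation was not separated from that of the test. Regrouping the same arrays without regard to genotype gave up to 19 lists past the threshold, so the preset-correlation calls below do not separate genotype from other differences between these 6 animals.

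Antigen presentation transcripts were the lowest group. All 11 measured genes of the dendritic cell and MHC class II list were lower in the KO-labelled ureters, with a median log2 difference of -1.33 (camera, adjusted p = 9.13e-10; adjusted p = 0.587 with an estimated correlation). Adjusted over the list alone, 10 of the 11 passed, and over all genes tested 0 did. H2-Ab1 and H2-Eb1, which encode class II beta chains, differed by -1.33 ± 0.28 and -1.38 ± 0.30, and Cd74, the invariant chain, by -1.34 ± 0.28. The array values did not overlap, although KO replicate 3, the female, had a list value of 0.02 where KO replicates 1 and 2 had -0.64 and -1.22. The monocyte and macrophage list was lower for 16 of 20 genes (median -0.53; camera, adjusted p = 1.97e-05; adjusted p = 0.59 with an estimated correlation). Adjusted over the list alone 6 of them passed, and over all genes 0 did. Adgre1, a macrophage surface receptor, differed by -0.89 ± 0.21, C1qc, a complement subunit, by -0.56 ± 0.13, and Mertk, a receptor for apoptotic cells, by -0.47 ± 0.09. KO replicate 3 lay within the WT range for this list, and WT replicate 2, the array with kidney transcripts, had the highest value, 0.52.

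The lists of superficial and basal urothelium, cell junctions and the hemidesmosome were higher and passed with the preset correlation, while the squamous differentiation list (12 of 16 genes higher, adjusted p = 0.104) and the epithelial antimicrobial defence list (7 of 13 higher, adjusted p = 0.899) did not pass. All 18 superficial urothelium genes were higher, with a median of 0.80 (camera, adjusted p = 4.21e-08; adjusted p = 0.587 with an estimated correlation), and 4 passed when adjusted over the list alone, against 0 over all genes. Krt7, Krt20 and Krt19, keratins of the urothelium, differed by 0.95 ± 0.20, 0.88 ± 0.21 and 0.82 ± 0.18. The array values of this list overlapped between groups: WT replicate 1, at 0.13, lay above KO replicate 3, at -0.08, and the lowest value, -0.87, belonged to WT replicate 2, the array with kidney transcripts, without which the median was 0.536. WT replicate 1 also stood with KO replicates 1 and 2 on the first principal component. Of 17 cell junction genes 15 were higher (median 0.65; camera, adjusted p = 6.66e-07; adjusted p = 0.587 with an estimated correlation), with 0 passing over the list alone. Dsp, which links desmosomes to keratin filaments, differed by 0.87 ± 0.24 and Perp by 0.85 ± 0.21. The hemidesmosome and basement membrane list, which holds the binding partners of collagen XVII, was higher for 14 of 15 genes (median 0.37; camera, adjusted p = 0.00177; adjusted p = 0.587 with an estimated correlation), with 0 passing over the list alone. Itgb4, an integrin chain of the hemidesmosome, differed by 0.82 ± 0.22 and Lama5 by 0.56 ± 0.18. Of 15 basal urothelium genes 12 were higher (median 0.40; camera, adjusted p = 0.00953; adjusted p = 0.587 with an estimated correlation). Krt5, a basal keratin, differed by 0.91 ± 0.19, while Trp63, a basal transcription factor, differed by -0.32 ± 0.10 at its brightest probe, and its other probes reached 0.88. The basal list lost its call with array weights (median 0.19, adjusted p = 0.266), as did the hemidesmosome list (median 0.134, adjusted p = 0.0511), and the cell junction median was 0.355. In an alternative chosen after the data were seen, without WT replicate 2 and KO replicate 3, the basal list had an adjusted p of 0.0562. Without WT replicate 1 the medians of the basal and hemidesmosome lists were 0.22 and 0.18, and without KO replicate 2 those of the hemidesmosome and cell junction lists were 0.24 and 0.41. With normexp background the basal, hemidesmosome and cell junction medians were 0.24, 0.22 and 0.36.

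**Figure D2:**
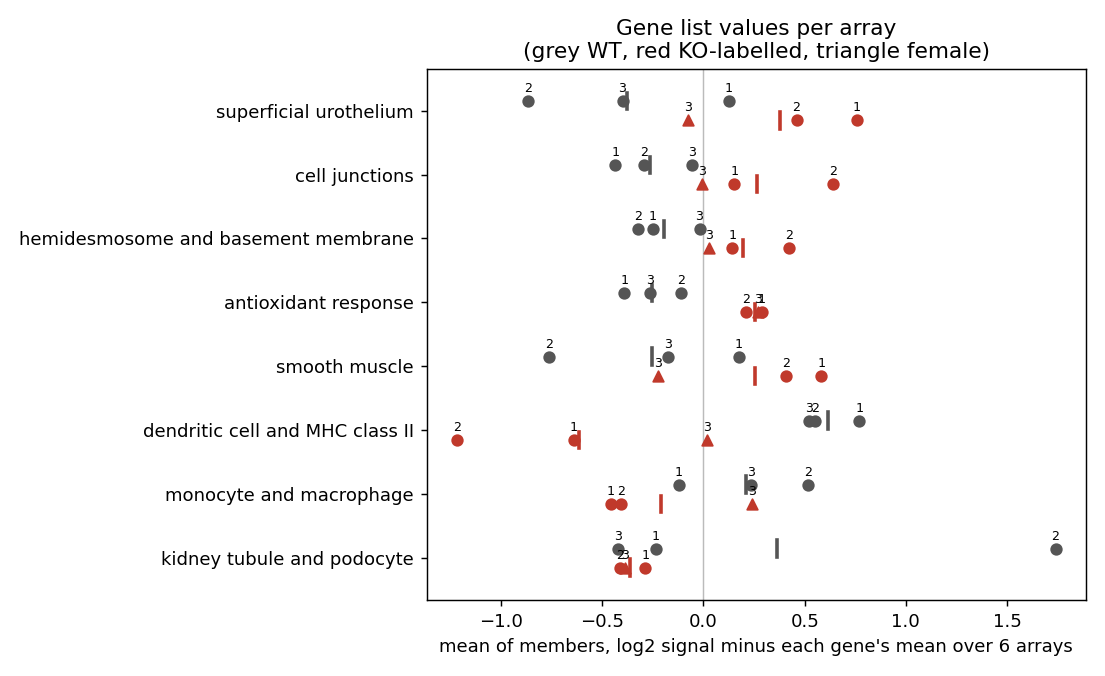
Mean of each list's measured members per array, as log2 signal minus each gene's mean over the 6 arrays, with points for arrays labelled by replicate number and vertical ticks for group means. WT replicate 2 stands at 1.74 on the kidney list, and KO replicate 3 lies nearest to WT on the MHC class II list.

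Detoxification and sterol genes were also higher. Of 12 antioxidant response genes 11 were higher (median 0.37; camera, adjusted p = 0.000182; adjusted p = 0.587 with an estimated correlation), with 3 passing over the list alone and 0 over all genes. Nqo1, a quinone reductase, differed by 1.45 ± 0.20, Gsta4, a glutathione transferase, by 1.13 ± 0.25 and Gclc, which makes glutathione, by 0.68 ± 0.19. The members of this list had an estimated correlation of 0.0174 with each other. Of 17 cholesterol synthesis genes 15 were higher (median 0.34; camera, adjusted p = 2.41e-06; adjusted p = 0.587 with an estimated correlation), and Sqle, a squalene epoxidase, differed by 0.54 ± 0.16. The array values of this list overlapped between groups, and the lowest belonged to WT replicate 2.

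Of the other lists past the preset-correlation threshold, the array values of the smooth muscle, Wnt, Notch, Hedgehog and kidney lists overlapped between groups, and those of the mesothelium and heat shock lists did not. On the smooth muscle, Wnt, Notch and Hedgehog lists WT replicate 2 had the lowest value and WT replicate 1 lay above KO replicate 3. All 16 smooth muscle genes were higher (median 0.44; camera, adjusted p = 8.68e-05; adjusted p = 0.639 with an estimated correlation), with 0 at an unadjusted p under 0.05 and Actg2 at 0.74 ± 0.35. Its median was 0.24 without WT replicate 2, 0.69 without WT replicate 1 and 0.67 without KO replicate 3 and with a sex covariate. The Wnt pathway list had a median of 0.50 (camera, adjusted p = 0.000646; adjusted p = 0.59 with an estimated correlation), and Wnt4 differed by 1.02 ± 0.20. Its median was 0.31 without WT replicate 2 and 0.20 with normexp background. The mesothelium list had a median of 1.04 over 5 genes (camera, adjusted p = 0.00972; adjusted p = 0.587 with an estimated correlation), led by Msln at 1.48 ± 0.35, and its median was 0.23 with normexp background. The heat shock list had a median of -0.32 (camera, adjusted p = 0.0105; adjusted p = 0.587 with an estimated correlation), and Hsph1 differed by -1.02 ± 0.20. It lost its call with a sex covariate (median -0.29, adjusted p = 0.0959), without WT replicate 3 (median -0.301, adjusted p = 0.0564), without KO replicate 3 (median -0.29, adjusted p = 0.0902) and without WT replicate 2 and KO replicate 3 together (median -0.186, adjusted p = 0.108). The Notch list (median 0.19; camera, adjusted p = 0.019; adjusted p = 0.587 with an estimated correlation) and the Hedgehog list (median 0.36; camera, adjusted p = 0.0301; adjusted p = 0.639 with an estimated correlation) lost their calls without WT replicate 2 (medians 0.138 and 0.124, adjusted p-values 0.156 and 0.195) and without KO replicate 2 (medians 0.113 and 0.166, adjusted p-values 0.0885 and 0.124). Without KO replicate 3, or with a sex covariate, which also removes that animal, their medians were 0.283 and 0.578. With normexp background their medians were 0.0929 and 0.11, and without WT replicate 1 the Hedgehog median was 0.575. The Hedgehog call was also lost without WT replicate 3 (median 0.372, adjusted p = 0.0663) and without KO replicate 1 (median 0.329, adjusted p = 0.0608), and both calls with the mean of a gene's probes (medians 0.177 and 0.358, adjusted p-values 0.119 and 0.0573). The Notch call was also lost without WT replicate 2 and KO replicate 3 together (median 0.247, adjusted p = 0.108). The kidney tubule and podocyte list had a median of -0.78 (camera, adjusted p = 0.0231; adjusted p = 0.639 with an estimated correlation), and its value was 1.74 in WT replicate 2 against -0.42 to -0.24 in the other 5 arrays. Without WT replicate 2 the median was 0.04 and the call was lost (adjusted p = 0.88), as it was without WT replicate 2 and KO replicate 3 together (adjusted p = 0.864), with array weights (median -0.08, adjusted p = 0.467), with normexp background (median -0.231, adjusted p = 0.0557) and with only probes well above background on all arrays (median -0.688, adjusted p = 0.185). The call was also lost without KO replicate 3 (adjusted p = 0.0725) and with a sex covariate (adjusted p = 0.0804), where the median stayed at -0.763, and the median was -1.4 without WT replicate 1. Slc34a1, a phosphate transporter of the kidney tubule, was -0.69 in WT replicate 2 and -4.69 and -4.99 in WT replicates 1 and 3.

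The remaining 24 lists did not pass, with adjusted p-values from 0.0649 for hypoxia and glycolysis to 0.947 for adipocyte genes. The fibroblast and collagen matrix list had a median of -0.03 over 20 genes, and Col1a1 differed by -0.15 ± 0.15. The T and NK cell list had a median of -0.06, the cell cycle list 0.10, and the inflammatory cytokine list -0.48 with array values between -1.08 and 1.04. Of 16 neutrophil genes 6 were higher and 10 lower, with a median of -0.05, a mean of 0.31 and an adjusted p of 0.198. Within the list, 3 genes passed when adjusted over the list alone, all higher: Ngp, which was not well above background on any WT array and was at least 3.62-fold higher, Ltf at 1.99 ± 0.37 and Camp at 1.17 ± 0.18.

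Genes close to Col17a1 on chromosome 19 differed more often than others. Within 10 Mb, 12 of 204 genes (5.88%) had an unadjusted p under 0.01, against 462 of 21946 elsewhere (2.11%), an odds ratio of 2.91 with a 95% interval of 1.47 to 5.24 (two-sided Fisher's exact test, p = 0.00155). The odds ratio was 4.75 within 5 Mb (9 of 97 genes) and 2.14 within 20 Mb (14 of 318 genes), with p = 0.000236 and p = 0.00997 in two-sided Fisher's exact tests. Neurl1a and Cfap43 were higher by 0.83 ± 0.11 and 1.42 ± 0.27, and Mfsd13a, Sfxn2 and Blnk were lower at -1.17 ± 0.20, -1.02 ± 0.20 and -1.42 ± 0.24, but a second Sfxn2 probe was higher by 0.335. Sfxn2, Mfsd13a and Neurl1a were chosen after their values were seen, and none of the 12 passed the adjusted threshold. Without KO replicate 3, the female, the share near the gene was 5.77% and that elsewhere 4.66%, the odds ratio was 1.25 and the call was lost (two-sided Fisher's exact test, p = 0.409).

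**Figure D3:**
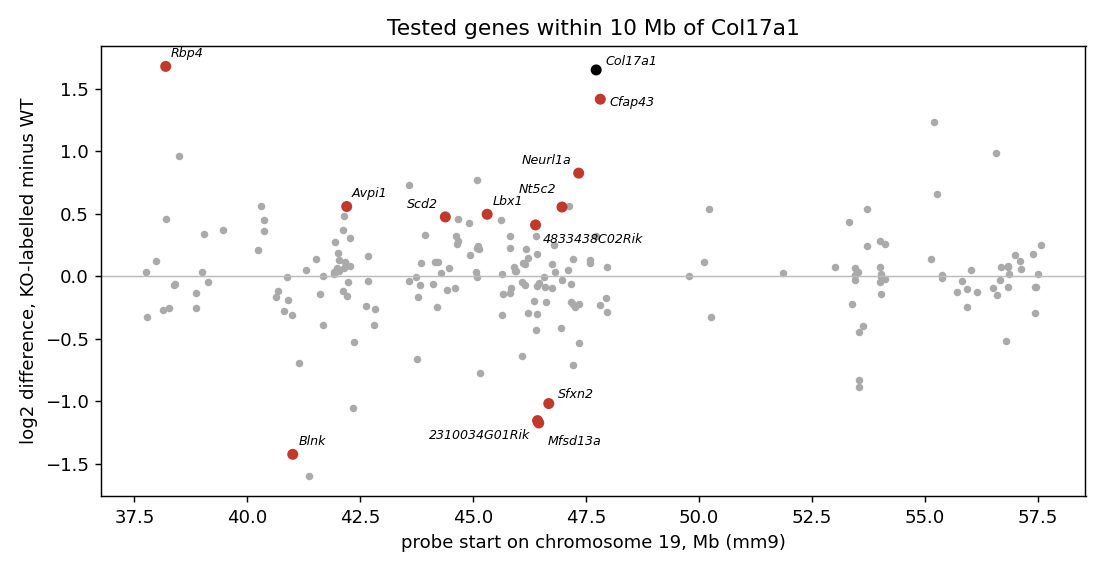
Log2 difference, KO-labelled minus WT, of tested genes against probe start on chromosome 19 (mm9, Mb) within 10 Mb of Col17a1, with genes at an unadjusted p under 0.01 in red, Col17a1 in black and all others in grey. Of the 12 red genes 8 are higher and 4 lower.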

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

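The alternative that left out both the WT array with kidney transcripts and the female KO array, and all alternatives for genes near Col17a1 except distance and call, were chosen after the data were seen. The count of genes past the threshold was 0 in most settings, also at an adjusted p under 0.10 and with at least a 2-fold change. It was 498 with array weights, whose estimation stopped before it converged and which weighted WT replicate 3 at 6.93 and WT replicate 1 at 0.23. Leaving out each array gave 0 to 1 genes; the 1 gene, without KO replicate 2, was the IgG1 constant region. Col17a1 stayed higher in the KO-labelled ureters, short of the threshold, in every setting, from 0.98 with array weights to 2.04 without WT replicate 3. The count of lists was 13 to 20 with the preset correlation, and 0 with an estimated correlation and 0 with fry; the estimated correlation gave 0 lists under every other setting too. The odds ratio for genes near Col17a1 was 1.26 with a sex covariate, which removes the female animal, and 1.85 without WT replicate 2 and KO replicate 3. Neither passed the threshold, and with each array left out the odds ratio was 1.25 to 4.06. Within 5 Mb it was 4.75 and within 20 Mb 2.14. The replicate numbers gave no consistent sign of pairing the samples. Deviations of same-numbered arrays correlated at 0.53, -0.15 and -0.03. The first of these was the highest of all pairs, but WT replicates 2 and 3 each correlated best with another number. With 3 arrays per group these correlations cannot exclude a pairing. With a replicate block 1 gene passed, the IgG2c constant region, and 15 lists did. No slide or scan block could be run, since there was 1 slide and 1 scan.

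Named genes changed sign in 11 of 2728 values: Trp63 (0.39) and Notch1 (-0.25) with the mean of a gene's probes; Jchain (-0.20), Csf3 (-0.60), Sdhb (0.044) and Slc34a1 (0.12) with array weights; Lipe (0.082) and Slc34a1 (0.34) without WT replicate 2 and KO replicate 3; and, with each array left out, Csf3 (-0.20 to 2.21) and Sdhb (-0.28 to 0.087), which turned without WT replicate 1, and Slc34a1 (-2.76 to 0.34), which turned without WT replicate 2. Another 41, all with array weights, passed the threshold. Where a setting moved a value, the cause was not tested. Signal near background limits dim genes such as Ngp.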

Other observations

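The tests of the chromosome segment, of variants for the higher genes, of the epithelial share, of leukocytes, of the female animal and of the immunoglobulin genes were chosen only after the results were seen. Immunoglobulin genes were also chosen after their values were seen. The constant regions of IgG2c, IgG1 and IgG2b had the largest differences among them, all higher in the KO-labelled ureters. IgG2c differed by 4.60 ± 0.49 (limma, adjusted p = 0.229) and IgG2b by 4.29 ± 0.50 (adjusted p = 0.31), and in both all 3 KO-labelled arrays lay above all 3 WT arrays. IgG1 was not well above background on any WT array and was at least 4.93-fold higher. The kappa constant region differed by 0.74 ± 0.23, while an IgM constant region transcript differed by -1.16 ± 0.42. A second IgM entry differed by -0.67 ± 0.43, IgG3 by 0.36 ± 0.23 and IgA by 0.30 ± 0.62, each with overlap between groups. Of 52 immunoglobulin entries 46 were higher, 19 of them at an unadjusted p under 0.05 in limma, and none passed the adjusted threshold. Over all 22260 genes, 969 were higher at an unadjusted p under 0.05. Some of the 52 entries belong to the same gene, and some passed the filter only through the KO-labelled arrays, where they were high. The count therefore overstates a joint rise.

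For the IgG pattern, a sequence variant under a single probe is argued against, since 2 of 2 further IgG2c probes were higher too. A variant of the heavy chain locus alone would not account for higher kappa genes, which lie on another chromosome. Their median difference was 0.837. Some of them passed the filter only through the KO-labelled arrays, where they were high, so this median overstates their rise and cannot decide the question. Kappa genes well above background on every array differed by -0.87 to 1.07. The kappa constant region, 1 of these, differed by 0.74 ± 0.23 with no overlap between groups, short of the adjusted threshold. For the IgG genes themselves a different heavy chain haplotype stays open. The B and plasma cell list did not pass (camera, adjusted p = 0.581; adjusted p = 0.876 with an estimated correlation), with 3 of 9 genes higher, among them Jchain, which joins IgM and IgA chains, at 0.73 ± 0.44. These values neither support nor exclude more IgG-producing plasma cells in the KO-labelled ureters, which may remain as a hypothesis, as may a difference in the animals' immune history unrelated to genotype, which was not tested.

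For the lower MHC class II transcripts, an equal fall of all leukocytes as the whole source is argued against. The MHC class II list minus the T and NK cell list differed by -1.03 with a standard error of 0.12. The MHC class II list was tested because it was lowest, which favours such a difference. A leukocyte loss as part of the pattern is not excluded. T and NK cell list values were -0.22 and -0.52 in KO replicates 1 and 2, below all WT arrays, and 0.45 in KO replicate 3. The pattern did not rest on the female animal, since the median without it was -1.56. That animal was already known as the KO-labelled array nearest to WT on this list, so a larger difference without it could be foreseen. The value does not measure an effect of sex. Whether the real grouping explains the list calls stays open. Of the 10 splits of the 6 arrays 6, the real one included, gave at least 15 lists, and the highest of the other splits gave 19. The real count is thus not set apart, and 10 splits are too few for a share under 0.05. These counts cover all lists and do not bear on the MHC class II list by itself. Fewer dendritic cells or macrophages, or lower class II expression per cell, may each underlie the pattern as hypotheses.

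For the genes near Col17a1, variants under the probes cannot be told apart from other sources. A mismatch lowers signal in the carriers of a variant, and 8 genes were higher with no overlap in the KO-labelled ureters, but Col17a1 goes against the labels, so they do not show which group carries the altered segment. Cfap43 and Nt5c2, both higher, each had a second measured probe, which was higher too, by 1.69 and 0.399. Of the 4 lower genes only Sfxn2 had a second measured probe, which differed by 0.335 in the other direction, so 0 second probes were lower. A chromosome segment that travels with the altered gene may fit, as 0.231% of 20350 overlapping windows on other autosomes held as high a share, but the share near Col17a1 stood out only while the female KO array was included. The other splits reached 24 genes near Col17a1 against 12 in the real one, and 2 of 10 splits, the real one included, gave at least 12. The split with 24 called 1727 genes in all and had an odds ratio of 1.61, against 2.91 in the real one, and the highest of the other splits was 2.81 with 1 gene near Col17a1; 10 splits are too few for a share under 0.05. Whether a larger share of basal epithelium is the whole source of the higher Col17a1 signal cannot be told apart: Col17a1 minus 30 partner genes still differed by 1.22 with a standard error of 0.49, but this was 0.741 without WT replicate 1, and the partner genes themselves differed by -0.324 to 1.78, a range that holds Col17a1 at 1.65. A signal from a part of the gene left intact, or a mislabelled group, was not tested.

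The 10 splits also bear on the gene counts, and are too few for a share under 0.05. The real split gave 0 genes past the threshold, which any split matches, and 478 at an unadjusted p under 0.01, which 2 of 10 splits, the real one included, reached. The highest of the others, WT replicate 1 with KO replicates 1 and 2 against the rest, gave 19 and 1727, which points to a structure of the samples other than genotype. The same 3 arrays stood together on the first principal component, which held 42.5% of the variance, at -33.6, -33.8 and -22.3 against 20.3 to 48.5. On the second component, which held 31.6%, the labelled groups did not overlap. There the WT arrays lay at -50.6, -9.85 and 1.47 and the KO-labelled arrays at 14.3, 39.4 and 5.26, with replicate 3 of each group close together.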
